A study of Solanum lycopersicum x Solanum pennellii and Solanum lycopersicum with 17 samples.

How the data were processed

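RNA from tomato carpels collected 7 days after pollination was hybridised, 1 sample per array, to an Affymetrix tomato genome array after biotin labelling by the single-cycle protocol, per the labels. The series holds 17 arrays in 4 groups. The control is the cultivar M82 with 6 arrays, named a seed control in the sample titles. The 3 introgression lines are IL-1_1 with 4 arrays, IL-1_4 with 3 and IL-2_3 with 4. An introgression line carries a defined chromosome segment of the wild relative Solanum pennellii in an M82 background, and the number after IL is that of the chromosome. The design text calls the lines hybrids, and nothing in the sources used here settles whether the plants sampled were homozygous or hybrid for the segment. Nothing states that the replicates came from separate plants, so the p-values measure only the spread between these samples, which can be technical.

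The deposited log2 values are the authors' processed probe set intensities, 1 column per array, and were used as they stood. Per the submitters' processing notes the tool was affy; its version and the background and summarization methods are not given in the sources used here. The log base is not stated either: base 2 was inferred from the range of the values, 3.31 to 14.75, and a different base would rescale every log2 change while leaving the calls as they are. The distributions of the arrays were nearly equal, with an SD between arrays of at most 0.0724 at any rank and array medians between 9.97 and 10.045, so no further normalization was applied. The table held 10209 probe sets. The 108 control probe sets were left out, and 10101 were tested.

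Names come from the platform annotation of 2007, which gives gene symbols without descriptions. Of the tested probe sets 909 (9% of all) had 1 symbol, 0 had several and 9192 had none. They carry 802 distinct symbols, and 207 of the named probe sets bear a number in place of a symbol (LOC543740, for example). A probe set without a symbol is unnamed here, which does not mean that it has no gene.

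Each line was compared with M82, and each pair of lines with each other, in a single limma fit over all 17 arrays with 1 mean per group, no covariate and a two-sided moderated test (limma 3.58.1, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over the 10101 probe sets of a comparison, and a probe set was called at a false discovery rate of 0.05. Errors of log2 changes are the standard errors of that fit, levels are given as mean ± SD over arrays, and intervals are at 95%. The 3 comparisons share the M82 arrays, so overlaps between them were set beside 100 simulations of unchanged lines and beside the overlap of independent lists. They were also set beside all 20 ways of giving 3 of the M82 arrays to 1 line of a pair and the rest to the other. The number of arrays limits the precision of every value.

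The design, the rule for named genes and 27 gene lists, written as patterns over gene names, were fixed before the data were examined. Only 4 of those 27 lists (cell cycle, auxin, ethylene, MADS-box and floral identity) matched the minimum of 5 probe sets, because the annotation held symbols alone. Lists of symbols were therefore written after the table of names was seen and before any comparison was computed. They cover cell cycle, photosynthesis, auxin, gibberellin, ethylene, abscisic acid and water stress, cell wall, jasmonate and wound, pathogenesis-related, heat shock, antioxidant, phenylpropanoid, carotenoid and plastid isoprenoid, sugar and starch, MADS-box, meristem and organ shape, light signalling, 14-3-3, small GTPase and ribosomal protein genes and pollen markers, 21 in all. Markers of style and stigma and of young fruit were too few to test as lists. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, and again with a correlation estimated from the data. Adjustment ran over the 12 tests of the 4 pattern lists and over the 63 tests of the 21 symbol lists.

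The genes named for a line against M82 are the called probe sets with a symbol whose line arrays all lie above, or all below, every M82 array. The 10 with the largest rise and the 10 with the largest fall were taken, or all where fewer passed, with 1 probe set per gene. Added to these are up to 4 called members of each list, or the 2 members with the smallest p where none was called. For a pair of lines the 3 largest changes each way were taken. Any gene or probe set named outside this rule is said to be so.

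The fit was tested on simulated data with 50 probe sets changed at each of 4 sizes among 10101. At log2 changes of 0.5, 1, 2 and 4, it recovered 42%, 88%, 94% and 100% of them for IL-1_1 against M82. For IL-1_4 against M82 it recovered 22%, 66%, 88% and 100%, and for IL-2_3 against M82 34%, 80%, 96% and 100%. False calls made up 2.2%, 2.8% and 4.9% of the calls. A list shifted in the simulated IL-1_1 arrays was recovered, and no list was called in the other simulated lines. The simulated noise was independent between probe sets, so it lacks the variation that many probe sets of the real arrays share. These rates therefore do not show how the fit and the list test behave under such shared variation.

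The alternatives were quantile normalization, centring of each array on its median, removal of the dimmest 25% of probe sets, a variance trend, a fit of only the 2 groups compared, the replicate number as a block, each array left out in turn, and the estimated correlation for lists. Chosen after seeing the data were 3 more: leaving out M82 replicate 5 and IL-1_4 replicate 1, whose 3-prime to 5-prime control differences were the highest; leaving out M82 replicate 1, IL-1_1 replicate 1 and IL-2_3 replicate 4, each the lowest of its group on the first principal component, though IL-1_1 replicates 3 and 4 lay lower than the IL-2_3 array; and a covariate for the main axis of variation within groups. That axis was computed from the deviations of the M82, IL-1_4 and IL-2_3 arrays from their group means, and all 17 arrays were scored on it. Tests of enrichment of the called genes on the introgressed chromosomes, and counts without the genes of those chromosomes, were not run because no table of chromosome positions was used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.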

Results

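Gene expression was measured in whole carpels of tomato 7 days after pollination, when the ovary has begun to grow into a fruit with young seeds. M82 (n = 6) was the reference, and the introgression lines IL-1_1 (n = 4), IL-1_4 (n = 3) and IL-2_3 (n = 4) were each compared with it. Array medians ranged from 9.97 to 10.045 on the log2 scale. Correlations between arrays of the same group were 0.95 to 0.996, and those between groups 0.913 to 0.991. The first principal component held 45.7% of the variance; arrays of M82 and IL-2_3 spread widely along it, and the IL-1_1 arrays lay toward 1 end, with M82 replicate 1 and IL-2_3 replicate 4 among them. Along the main axis of variation within the other groups, IL-1_1 arrays had a mean score of 24.89 and M82 arrays of -8.24. An exact two-sided permutation test over the 210 splits of these 10 arrays gave p = 0.1 for that difference. The M82 arrays themselves ran from -36.73 to 43.25 on it, and IL-2_3 replicate 4 scored 33.29.

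**Figure D1:**
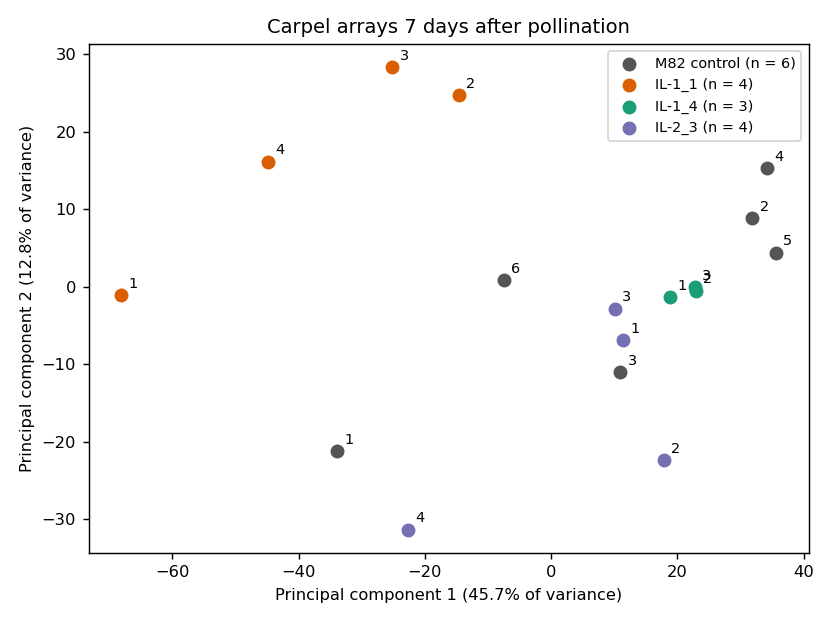
Scores of the 17 arrays on the first (horizontal, 45.7% of variance) and second (vertical, 12.8%) principal components of the log2 values, with 1 point per array, coloured by group and numbered by replicate. The IL-1_1 arrays lie at -68.06 to -14.57 on the first component, and the M82 arrays spread from -33.93 to 35.61.

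The lines were compared with M82 to find which transcripts of the growing carpel differ when a segment of the wild species is present. IL-1_1 differed most widely: 1233 of 10101 probe sets were called with limma, of which 646 were higher and 587 lower than in M82. IL-1_4 differed at 65 probe sets, with 13 higher and 52 lower, and IL-2_3 at 91, with 19 higher and 72 lower. Falls thus made up 47.6% of the calls in IL-1_1, 80% in IL-1_4 and 79.1% in IL-2_3. Calls in IL-1_1 were mostly of modest size, with a median absolute log2 change of 0.694, against 1.504 in IL-1_4 and 1.224 in IL-2_3. Changes of more than 4-fold numbered 57 up and 35 down in IL-1_1, 3 up and 18 down in IL-1_4, and 5 up and 25 down in IL-2_3. Only 131, 5 and 4 of the called probe sets carry a symbol.

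**Figure D2:**
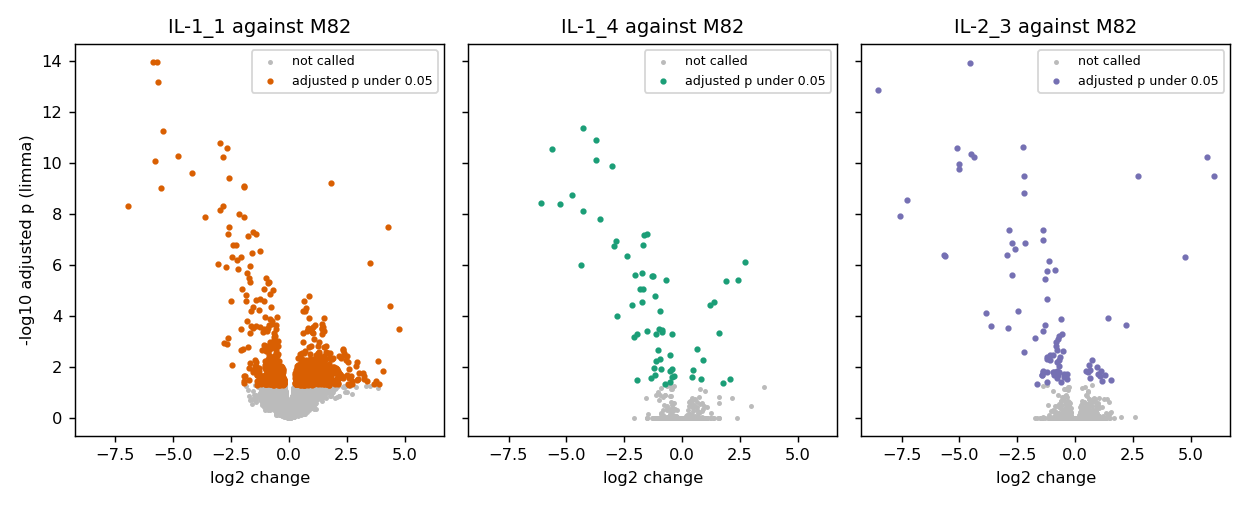
Log2 change against M82 (horizontal) and -log10 of the limma adjusted p (vertical) of the 10101 probe sets in each line, with 1 point per probe set and those called at 0.05 in colour. Calls number 1233 in IL-1_1, 65 in IL-1_4 and 91 in IL-2_3, and falls outnumber rises in IL-1_4 and IL-2_3.

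The number called in IL-1_1 depended on single arrays. It was 3079 without M82 replicate 1, 547 without M82 replicate 2, 725 without replicate 3, 595 without replicate 4 and 673 without replicate 5. It was 469 without IL-1_1 replicate 1 and 421 without IL-1_1 replicate 4. Fitting only the IL-1_1 and M82 arrays gave 377 calls, leaving out the pair of arrays with the highest 3-prime to 5-prime control differences gave 555, leaving out 3 arrays (M82 replicate 1, IL-1_1 replicate 1 and IL-2_3 replicate 4), each the lowest of its group on the first component, gave 1916, and the axis of variation within groups as a covariate gave 537. With each array centred on its median the calls were 607 higher and 775 lower. The fit over all 17 arrays uses 1 spread per probe set for all groups. The median SD was 0.232 in M82 and 0.221 in IL-1_1, but 0.184 in IL-2_3 and 0.114 in IL-1_4. The counts for IL-1_4 against M82 (48 to 70) and for IL-2_3 against M82 (68 to 100) moved far less when arrays were left out. The count for IL-1_4 was 104 with the axis covariate, and that for IL-2_3 was 60 with only its own arrays and those of M82.

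Among probe sets with a symbol whose arrays did not overlap with M82, the largest rises in IL-1_1 were those of CEVI57 and loxC. CEVI57 averaged 10.67 ± 1.27 (SD, n = 4) in IL-1_1 and 5.91 ± 0.74 (n = 6) in M82, a log2 change of 4.75 ± 0.66 (SE; limma adjusted p = 0.000326). The lipoxygenase gene loxC, whose enzyme makes precursors of fruit volatiles, averaged 10.43 ± 1.12 and 6.06 ± 0.65, a change of 4.37 ± 0.50 (adjusted p = 4.08e-05). Each lay above all 6 M82 arrays in all 4 IL-1_1 arrays. The largest falls among probe sets with a symbol were of LOC543740, from 12.003 ± 0.704 in M82 to 5.032 ± 0.060 in IL-1_1 (log2 change -6.97 ± 0.38, adjusted p = 4.76e-09), and of the subtilisin-like protease gene sbt4a, from 9.46 ± 0.53 to 3.94 ± 0.09 (-5.52 ± 0.27, adjusted p = 9.91e-10). The sbt4a level in IL-1_1 is near the lowest values of the arrays (3.307 to 3.601), so its fall is a lower bound. A related gene, sbt3, fell by 0.82 ± 0.16 (adjusted p = 0.0075). The paralogous carotenoid cleavage dioxygenase genes moved apart: CCD1A rose by 1.80 ± 0.08 (adjusted p = 5.98e-10) and CCD1B fell by 2.29 ± 0.16 (adjusted p = 1.7e-07). TAO2 fell by 2.42 ± 0.17 and formin-I2I by 2.25 ± 0.18, with adjusted p of 1.7e-07 and 6.64e-07. Also changed were tXET-B2, a xyloglucan endotransglycosylase gene (2.56 ± 0.50), the auxin-response gene IAA7 (1.02 ± 0.19), ERF-H1 (-1.43 ± 0.28) and LOC543715 (-0.80 ± 0.17), with adjusted p of 0.00613, 0.00472, 0.00616 and 0.0103. All of these kept their call in every alternative that included them and with any 1 array left out. CEVI57, loxC, formin-I2I and IAA7 were among the dimmest 25% of probe sets, so the alternative without those holds no value for them. Another probe set of IAA7, with a level of 4.172 in M82, gave 0.26 (adjusted p = 0.0508) and was not called. Less secure were LOC778362 (2.95 ± 0.83, adjusted p = 0.0336), LOC544264 (2.06 ± 0.54, 0.0274) and yfe37 (-1.24 ± 0.33, 0.0265). Each was lost without M82 replicate 2, 4 or 5 or IL-1_1 replicate 1 or 4, and LOC778362 and yfe37 also without M82 replicate 3. LOC778362 was lost without IL-1_1 replicate 2 too. Their highest adjusted p with 1 array left out was 0.103, 0.0933 and 0.0969. Without the pair of arrays with raised 3-prime to 5-prime control differences it was 0.0833, 0.0716 and 0.0671, and with the axis covariate 0.192, 0.0584 and 0.152. With only IL-1_1 and M82 fitted, LOC544264 (0.0728) and yfe37 (0.102) were lost. The change of LOC544264 was 0.96 with the axis covariate, that of yfe37 -0.80 without IL-1_1 replicate 1, and that of LOC543715, still called, -0.53 without the 3 arrays lowest of their groups on the first component.

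**Figure D3:**
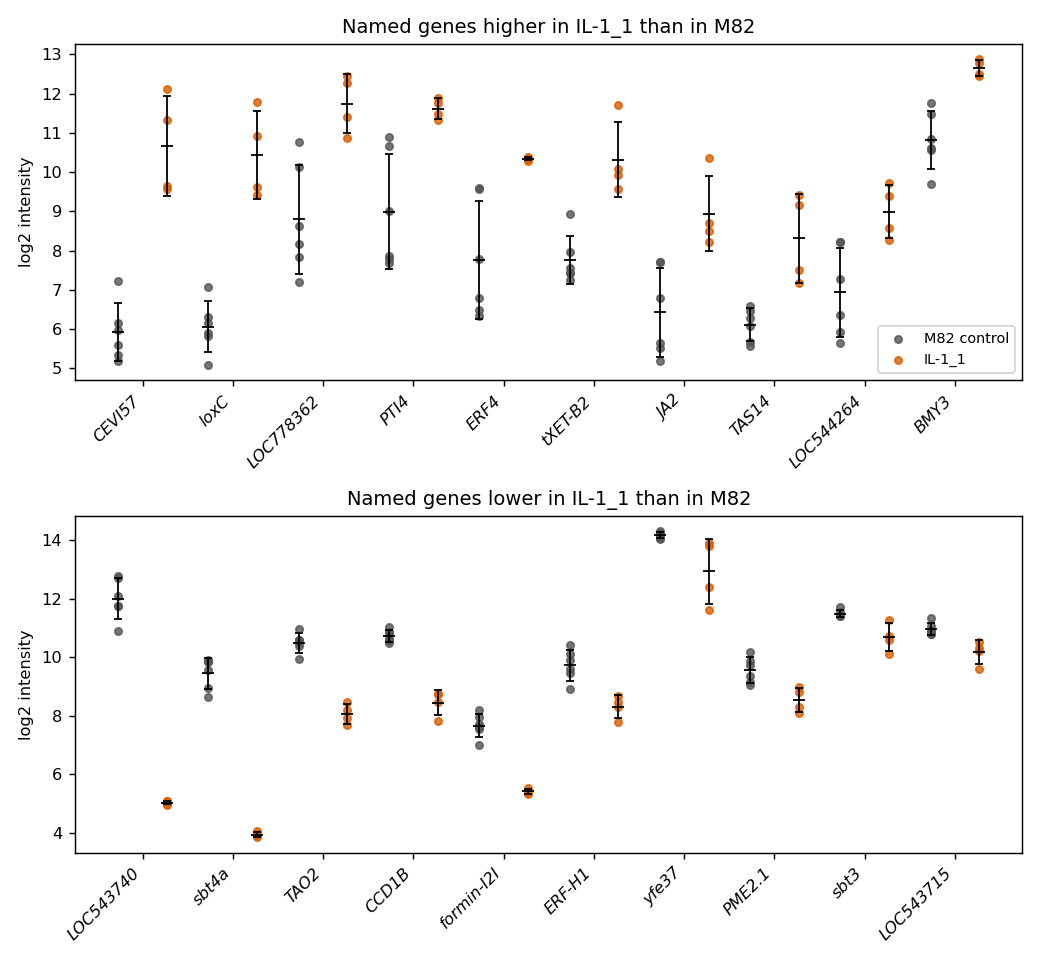
Log2 intensity (vertical) of the 10 named genes with the largest rise (top) and the 10 with the largest fall (bottom) in IL-1_1, with 1 point per array, and the mean and SD of M82 (n = 6) and IL-1_1 (n = 4) as black bars. LOC543740 averages 12.003 in M82 and 5.03 in IL-1_1, and CEVI57 averages 5.91 and 10.67.

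Ethylene genes were higher in IL-1_1 as a list at the preset correlation only, and few of them were called. Of the 26 probe sets of the pattern list, 22 had a positive change, with a median of 0.24 (limma camera adjusted p = 0.00937), and 2 were called higher, as were 2 when adjusted over the list alone. The adjusted p was 0.586 with an estimated correlation and 0.25 with the axis covariate, where the median was 0.07; without the dimmest 25% of probe sets the list kept its call and its median was 0.47. Of the 33 probe sets of the symbol list, 28 were positive, with a median of 0.22 (adjusted p = 0.0259; adjusted p = 0.956 with an estimated correlation and 0.649 with the axis covariate, where the median was 0.06), and 0 were called when adjusted over the list alone. That call was also lost without M82 replicate 2 (adjusted p = 0.0704) and without IL-1_1 replicate 1 (0.0681). The called members were the ethylene response factor gene ERF4, which rose by 2.58 ± 0.68 (limma adjusted p = 0.0265), and EIL3, of the EIN3-like family of transcription factors, by 1.55 ± 0.44 (adjusted p = 0.0364). PTI4, another ERF gene but one that neither list holds, rose by 2.63 ± 0.67 (limma adjusted p = 0.024). Also outside both lists, ERF-H1, an ERF gene by its symbol, went the other way (-1.43 ± 0.28, limma adjusted p = 0.00616). Its call was kept in every alternative. The probe sets of ACO6, an ACC oxidase gene of ethylene synthesis, gave 2.52 ± 0.98, 3.31 ± 1.08 and 3.47 ± 1.15 (adjusted p = 0.0918, 0.0557 and 0.0582) and were not called; ACO6 stands outside the naming rule and was picked after its values were seen. ERF4 levels ran from 6.34 to 9.61 among M82 arrays and from 10.29 to 10.39 in IL-1_1, and PTI4 and ERF4 move along the axis of variation within groups. With that axis as a covariate the changes of PTI4, ERF4 and EIL3 were 1.58, 1.36 and 0.62, and the adjusted p was 0.129, 0.115 and 0.0645. All 3 calls were lost without M82 replicate 2, 4 or 5 or IL-1_1 replicate 1 or 4, and EIL3 also without M82 replicate 3 or IL-1_1 replicate 3. Their highest adjusted p there was 0.0626, 0.0723 and 0.105, and leaving out the pair of arrays with raised 3-prime to 5-prime control differences (0.068, 0.0708 and 0.0917) or fitting only IL-1_1 and M82 (0.0597, 0.0636 and 0.094) ended them too.

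No stress or defence list was called in IL-1_1, but several held called members. In the abscisic acid and water stress list, 2 of 9 probe sets were called higher and 8 were positive, with a median of 0.56 (limma camera adjusted p = 0.0508, not called). The dehydrin gene TAS14 rose by 2.20 ± 0.54 (limma adjusted p = 0.0205) and the bZIP factor gene AREB1 by 1.21 ± 0.31 (0.024). In the jasmonate and wound list 2 of 23 were called higher, loxC and the NAC factor gene JA2 (2.51 ± 0.62, adjusted p = 0.0204). The median of that list was -0.07 while its mean was 0.32 and its test pointed up (camera adjusted p = 0.689). The chitinase gene CHI14 rose by 0.98 ± 0.23 (adjusted p = 0.0143), as the single call among 14 pathogenesis-related probe sets. HSP21, a small heat shock protein gene, fell by 1.25 ± 0.32 (0.0236; 1 of 7), and the catalase gene CAT2 rose by 0.24 ± 0.07 (0.041; 1 of 20 antioxidant probe sets). Without IL-1_1 replicate 1 the adjusted p was 0.0798 for TAS14, 0.0896 for AREB1, 0.0795 for JA2, 0.0533 for CHI14, 0.0857 for HSP21 and 0.0893 for CAT2. Without IL-1_1 replicate 4 it was 0.0602 for AREB1, 0.0621 for CHI14, 0.0775 for HSP21 and 0.0802 for CAT2. Without M82 replicate 2 it was 0.0575 for AREB1, 0.0501 for JA2, 0.0552 for HSP21 and 0.091 for CAT2. AREB1 was also lost without M82 replicate 4 (0.0536) or 5 (0.0511), HSP21 without M82 replicate 4 (0.0513), and CAT2 without 8 further arrays taken 1 at a time (0.0533 to 0.0856): M82 replicates 3, 4 and 6, IL-1_1 replicate 2, all IL-1_4 arrays and IL-2_3 replicate 1. With the axis covariate TAS14 (0.0858), JA2 (0.0799), CHI14 (0.0754) and HSP21 (0.0891) were not called. The changes of JA2, HSP21 and AREB1, the last still called, were then 1.40, -0.67 and 0.57. With only IL-1_1 and M82 fitted AREB1 (0.0812), JA2 (0.0535), CHI14 (0.0576), HSP21 (0.0649) and CAT2 (0.105) were lost, and CAT2 also with median centring (0.0618). Without the arrays with raised 3-prime to 5-prime control differences the adjusted p was 0.055 for TAS14, 0.0667 for AREB1, 0.0603 for JA2, 0.0505 for HSP21 and 0.0642 for CAT2.

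No list of cell wall, sugar and starch, MADS-box or cell cycle genes was called in IL-1_1, but each held called members. Among 51 cell wall probe sets 4 were called higher and 4 lower, with a median of -0.12 (camera adjusted p = 0.689). XTH3 rose by 2.29 ± 0.58 (limma adjusted p = 0.0236) beside tXET-B2. The mannanase gene MAN2 fell by 1.95 ± 0.59 (0.0434) and the pectin methylesterase gene PME2.1 by 1.02 ± 0.23 (0.0132). Of 26 sugar and starch probe sets 5 were called higher and 3 lower. Its median of -0.08 and its test (0.989, pointing down) differ in sign from its mean of 0.12. The 3 probe sets of BMY3, a beta-amylase gene by its symbol, rose by 1.83 ± 0.35, 1.63 ± 0.35 and 1.30 ± 0.31 (0.00481, 0.0108 and 0.0185), and CIF1, an inhibitor of cell wall invertase, rose by 1.16 ± 0.33 (0.0341). The MADS-box genes TDR8 (3.03 ± 0.72, 0.0166) and TDR4 (1.31 ± 0.37, 0.0356) rose. They were 2 of 6 probe sets in the pattern list (median 0.19, camera adjusted p = 0.147, 3 higher when adjusted over the list alone) and 2 of 8 in the symbol list (0.32, 0.17). TDR4 was higher by a similar amount in IL-1_4 and IL-2_3 against the same M82 arrays, as given below, though not called there. Its rise is therefore not shown to be particular to IL-1_1. The cell cycle genes PCNA, the sliding clamp of DNA replication, and CDKB1, a mitotic cyclin-dependent kinase, fell by 0.67 ± 0.17 (0.0265) and 0.70 ± 0.22 (0.0493). They were 2 of 13 in the symbol list (median -0.19, camera adjusted p = 0.448). In the cell cycle pattern list of 5, 0 were called and 3 were lower when adjusted over the list alone (median -0.68, 0.147).

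These calls were mostly sensitive to 1 array. Without IL-1_1 replicate 4 the adjusted p was 0.085 for XTH3, 0.117 for MAN2, 0.0532 for PME2.1, 0.103 for CIF1, 0.0604 for the weakest BMY3 probe set, 0.0631 for TDR8, 0.104 for TDR4, 0.0954 for PCNA and 0.117 for CDKB1. Without IL-1_1 replicate 1 it was 0.083 for XTH3, 0.131 for MAN2, 0.0941 for CIF1, 0.057 for that BMY3 probe set, 0.057 for TDR8, 0.125 for TDR4, 0.0806 for PCNA and 0.174 for CDKB1. Without M82 replicate 2 it was 0.0614 for MAN2, 0.0756 for CIF1, 0.0804 for TDR4, 0.0615 for PCNA and 0.103 for CDKB1. Leaving out M82 replicate 3, 4 or 5 ended CIF1 (0.0596, 0.0598 and 0.065), TDR4 (0.0589, 0.0702 and 0.0712) and CDKB1 (0.0913, 0.0786 and 0.0964). Replicates 3, 5 and 6 of M82 each ended MAN2 (0.0825, 0.0866 and 0.0537), and replicate 5 ended PCNA (0.0554). IL-1_1 replicate 3 ended MAN2 (0.0697) and CDKB1 (0.0783), IL-1_4 replicate 1 ended MAN2 (0.0562), and the IL-1_4 arrays (0.0632 to 0.0648) and IL-2_3 replicates 1, 3 and 4 (0.0502 to 0.0557) each ended CDKB1. With the axis covariate the adjusted p was 0.0741 for XTH3, 0.099 for MAN2, 0.198 for CIF1, 0.0897 for TDR8, 0.205 for TDR4, 0.148 for PCNA and 0.236 for CDKB1. The 2 weaker BMY3 probe sets were at 0.0546 and 0.0921 there. The changes of TDR8, TDR4, CIF1 and the weakest BMY3 probe set were then 1.98, 0.75, 0.72 and 0.79, while those of XTH3 and MAN2 were 2.27 and -2.08. With only IL-1_1 and M82 fitted it was 0.0712 for MAN2, 0.0563 for PME2.1, 0.0513 for CIF1, 0.066 for TDR8, 0.101 for TDR4, 0.0724 for PCNA and 0.107 for CDKB1. Without the arrays with raised 3-prime to 5-prime control differences it was 0.0512 for XTH3, 0.107 for MAN2, 0.0509 for the weakest BMY3 probe set, 0.0779 for CIF1, 0.0896 for TDR4, 0.072 for PCNA and 0.117 for CDKB1. Without the 3 arrays lowest of their groups on the first component MAN2 (0.108) and CDKB1 (0.0926) were lost. The strongest BMY3 probe set kept its call throughout.

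The remaining lists held few calls in IL-1_1. Auxin had 1 of 15 probe sets higher (IAA7; camera adjusted p = 0.684), and the auxin pattern list 1 of 14 (0.261; 2 higher and 1 lower when adjusted over the list alone). Carotenoid and plastid isoprenoid genes had 1 higher and 1 lower of 21, the CCD1 pair (0.684). Light signalling had 1 of 11 higher, COP1, and small GTPases 1 of 9 lower, RAN2A (-0.35 ± 0.11, limma adjusted p = 0.0468; lost without any 1 array other than M82 replicate 1 and IL-1_1 replicates 2 and 3, at up to 0.167). COP1 rose by 0.66 ± 0.18 (0.0319; lost without M82 replicate 2, 3, 4 or 5 or IL-1_1 replicate 1 or 4, at up to 0.104). Photosynthesis (8 probe sets), gibberellin (9), phenylpropanoid (6), meristem and organ shape (8), 14-3-3 (7) and ribosomal protein genes (6) and pollen markers (6) had 0 called, with camera adjusted p of 0.968, 0.689, 0.733, 0.689, 0.684, 0.344 and 0.878. For photosynthesis genes and pollen markers the median, mean and test differed in sign (-0.08, -0.12 and up; 0.04, -0.12 and up). RNALE, a ribonuclease gene placed with the markers of style and stigma though its product is not known to be specific to them, rose by 1.70 ± 0.42 (limma adjusted p = 0.0205; 0.0801 without IL-1_1 replicate 1), as did fsm1 of the young fruit markers by 2.01 ± 0.59 (0.0393). fsm1 was lost without M82 replicate 2, 3, 4 or 5, IL-1_1 replicate 1, 3 or 4, IL-1_4 replicate 2 or 3 or IL-2_3 replicate 1, at up to 0.114. With only IL-1_1 and M82 fitted the adjusted p was 0.0724 for COP1, 0.128 for RAN2A, 0.0889 for RNALE and 0.11 for fsm1. Without the arrays with raised 3-prime to 5-prime control differences it was 0.0728 for COP1, 0.104 for RAN2A and 0.0932 for fsm1. With the axis covariate it was 0.107, 0.253 and 0.214 for those 3, with changes of 0.31, -0.20 and 0.98, and RNALE was at 0.0597 without the 3 arrays lowest of their groups on the first component.

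**Figure D4:**
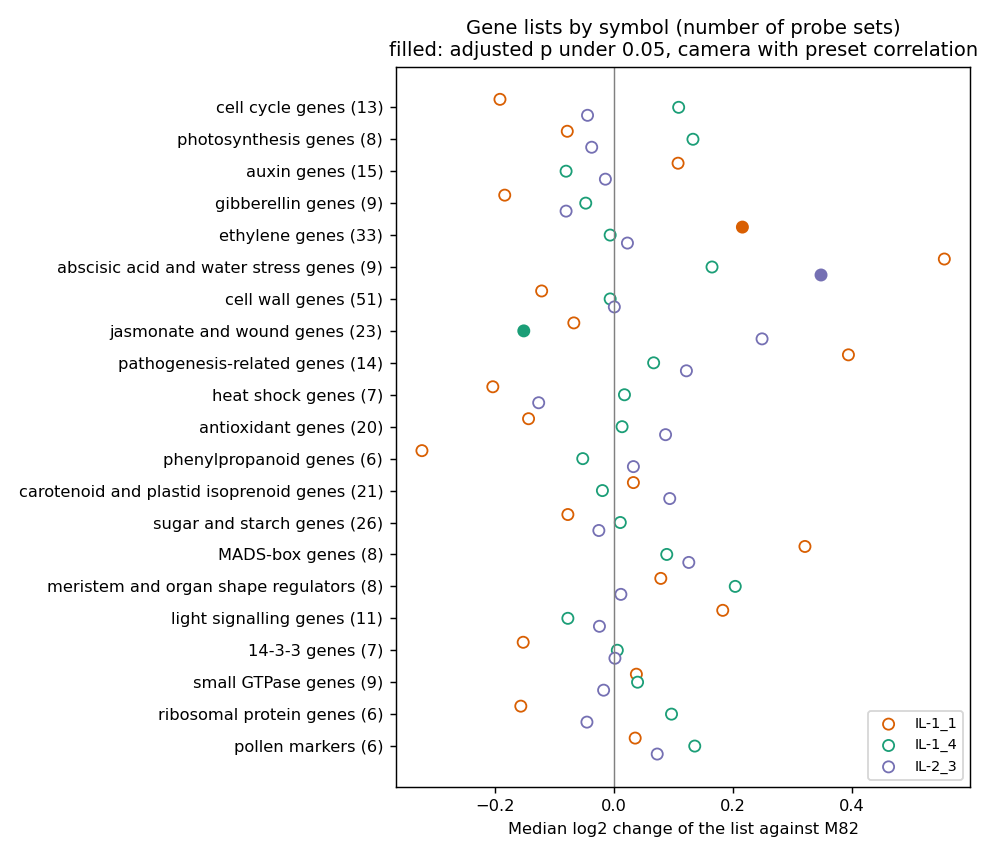
Median log2 change against M82 (horizontal) of the 21 symbol lists (vertical, with the number of probe sets) in IL-1_1, IL-1_4 and IL-2_3, filled where the camera adjusted p with the preset correlation was under 0.05. The filled points are ethylene genes in IL-1_1 (0.22), jasmonate and wound genes in IL-1_4 (-0.15) and abscisic acid and water stress genes in IL-2_3 (0.35), none of which was called with an estimated correlation.

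In IL-1_4 the 5 named changes were all falls, and 4 of them were of more than 4-fold. The monoterpene synthase gene MTS1 averaged 5.11 ± 0.26 (SD, n = 3) against 10.39 ± 0.44 in M82 (n = 6), and so fell by 5.28 ± 0.27 (SE; limma adjusted p = 4e-09). The oxophytodienoate reductase gene opr2 fell by 3.71 ± 0.14, from 8.60 ± 0.20 to 4.89 ± 0.12 (adjusted p = 7.53e-11). RAN2A, for a GTPase of nuclear transport, fell by 3.03 ± 0.12, from 13.39 ± 0.15 to 10.35 ± 0.13 (adjusted p = 1.34e-10). ER24 fell by 2.15 ± 0.23 (adjusted p = 3.62e-05). All 3 IL-1_4 arrays lay below all M82 arrays for each, and these 4 calls held in every alternative that included them (ER24 was among the dimmest 25% of probe sets, which 1 alternative leaves out). The small fall of ribA (-0.53 ± 0.11, adjusted p = 0.0385) did not: 13 of the 17 arrays ended it when left out, with adjusted p of up to 0.399 without IL-1_4 replicate 3. It was kept without M82 replicate 1, IL-1_1 replicates 1 and 3 or IL-1_4 replicate 1, and was lost with median centring (0.0658), without the arrays with raised 3-prime to 5-prime control differences (0.0704) and with only the arrays of IL-1_4 and M82 (0.2).

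As a list, jasmonate and wound genes were lower in IL-1_4 at the preset correlation only. Of 23 probe sets 7 were positive, with a median of -0.15 (limma camera adjusted p = 0.0259). The camera adjusted p was 0.956 with an estimated correlation, and opr2 was the only member called. The list mean of -0.314 includes opr2 at -3.71. Whether the call of the list holds without opr2 was not tested. The call was lost without M82 replicate 1 (0.0997) or 5 (0.0589), without IL-1_4 replicate 3 (0.0518), without the 3 arrays lowest of their groups on the first component (0.148) and with the axis covariate (0.139). The median was -0.04 without M82 replicate 1 and without those 3 arrays, -0.07 with the axis covariate and, with the call kept, -0.09 without M82 replicate 6. In the other symbol lists, 1 probe set was called, RAN2A among the 9 of small GTPases, where the median of 0.04 differs in sign from the mean of -0.26. The pattern lists were not called in IL-1_4, though 1 was without M82 replicate 1, without IL-1_4 replicate 3 and without the 3 arrays lowest of their groups on the first component: cell cycle (0.485), auxin (0.261), ethylene (0.485) and MADS-box and floral identity (0.147). When adjusted over the list alone they held 0, 0, 0 and 1 called member, the last being TDR4 at 1.25 ± 0.41 (adjusted p = 0.622 over all probe sets). In the antioxidant (0.014, -0.043), sugar and starch (0.011, -0.004) and cell wall (-0.006, 0.036) lists the median and mean differed in sign as well, and none of these was called. Meristem and organ shape genes had a median of 0.20 (camera adjusted p = 0.0652).

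In IL-2_3 the largest named change was the loss of signal of ARF3, an auxin response factor by its symbol. It averaged 5.23 ± 0.41 (n = 4) against 10.24 ± 0.32 in M82 (n = 6), and so fell by 5.01 ± 0.21 (limma adjusted p = 1.76e-10). Another ARF3 probe set gave -0.07 (adjusted p = 0.999), so the fall holds for 1 of the 2 probe sets that measure the gene. LOC543598 rose by 2.19 ± 0.27, from 5.57 ± 0.57 to 7.76 ± 0.33 (adjusted p = 0.000224), while LOC543597 fell by 3.64 ± 0.46, from 9.13 ± 1.09 to 5.49 ± 0.47 (adjusted p = 0.000243). These 3 calls held in every alternative that included them (LOC543598 was among the dimmest 25% of probe sets, which 1 alternative leaves out). RPB2, for a large subunit of RNA polymerase II, fell by 0.68 ± 0.12 (adjusted p = 0.00515; 0.0528 with only the arrays of IL-2_3 and M82).

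No symbol list member other than ARF3 was called in IL-2_3. Abscisic acid and water stress genes were higher as a group, with 8 of 9 probe sets positive and a median of 0.35 (camera adjusted p = 0.0446), but the adjusted p was 0.956 with an estimated correlation. That call was lost without M82 replicate 1 (0.0682), 2 (0.0924), 3 (0.0688), 4 (0.0524) or 5 (0.0589), IL-1_4 replicate 3 (0.0518) or IL-2_3 replicate 1 (0.181) or 3 (0.0565). It was lost as well without the dimmest probe sets (0.163), without the arrays with raised 3-prime to 5-prime control differences (0.056) and with the axis covariate (0.0777). The median was 0.21 without IL-2_3 replicate 1 and, with the call kept, 0.58 without the 3 arrays lowest of their groups on the first component. TAS14 gave 1.09 ± 0.54 and AREB1 0.58 ± 0.31. In the MADS-box pattern list 5 of 6 were positive with a median of 0.20 (adjusted p = 0.0441; adjusted p = 0.586 with an estimated correlation), 0 were called, and 1 was higher when adjusted over the list alone. Without IL-2_3 replicate 1, 2 of the 4 pattern lists were called. This call was lost without M82 replicate 2 (0.0947), 4 (0.0609) or 6 (0.0833), IL-1_1 replicate 4 (0.0611) or IL-2_3 replicate 3 (0.135) or 4 (0.108), and with the axis covariate (0.0948). The symbol list of 8 MADS-box genes was not called (0.684), and its members included TDR4 at 1.38 ± 0.37 and AG1 at -1.21 ± 0.27 (limma adjusted p = 0.181 and 0.0533). Jasmonate and wound genes had a median of 0.25 in IL-2_3 (camera adjusted p = 0.0508). The pattern lists for cell cycle (0.485), auxin (0.147) and ethylene (0.723) were not called, with 0, 1 and 0 members called when adjusted over the list alone. The medians of the auxin pattern list (0.009), cell wall (0.001), phenylpropanoid (0.033), light signalling (-0.024) and 14-3-3 genes (0.002) and pollen markers (0.073) differ in sign from their means (-0.406, -0.079, -0.008, 0.004, -0.01 and -0.052). The tests of phenylpropanoid genes and pollen markers pointed up and the other 4 down, and none was called.

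**Figure D5:**
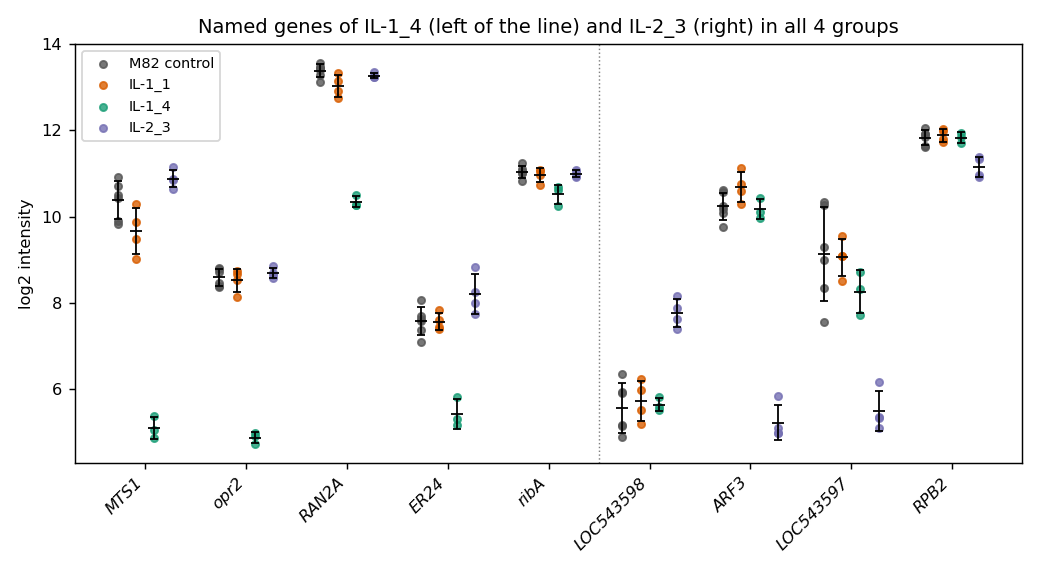
Log2 intensity (vertical) of the named genes of IL-1_4 (left of the dotted line) and IL-2_3 (right) in all 4 groups, with 1 point per array and black bars for mean and SD (n = 6, 4, 3 and 4). MTS1 averages 5.11 in IL-1_4 and 10.39 in M82, and ARF3 averages 5.23 in IL-2_3 and 10.24 in M82.

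The lines were then compared with each other, which tests whether a change belongs to a line. MTS1 was higher in IL-1_1 than in IL-1_4 by 4.56 ± 0.29 (limma adjusted p = 2.99e-08) and lower in IL-1_4 than in IL-2_3 (-5.78 ± 0.29, adjusted p = 1.76e-09). The opr2 and RAN2A genes were lower in IL-1_4 than in IL-2_3 as well, by -3.81 ± 0.15 and -2.92 ± 0.13 (adjusted p = 1.05e-10 and 3.7e-10). ARF3 was higher than in IL-2_3 in both IL-1_1 (5.47 ± 0.23, adjusted p = 1.21e-10) and IL-1_4 (4.94 ± 0.24, adjusted p = 1.65e-09). CEVI57 was higher in IL-1_1 than in IL-1_4 (5.49 ± 0.78, adjusted p = 0.000336) and IL-2_3 (4.403 ± 0.722, adjusted p = 0.00135), and loxC than in IL-2_3 (4.11 ± 0.54, adjusted p = 0.000167). LOC543740 and sbt4a were lower in IL-1_1 than in either, by -7.06 ± 0.45 and -5.76 ± 0.31 against IL-1_4 and by -7.77 ± 0.41 and -5.38 ± 0.29 against IL-2_3, with adjusted p of 2.93e-08 or less, those of sbt4a being lower bounds because of its level in IL-1_1. CCD1B was lower in IL-1_1 than in IL-2_3 (-2.58 ± 0.18, adjusted p = 7.88e-08). Dea1 was lower in IL-1_1 than in IL-1_4 (-3.25 ± 0.71, adjusted p = 0.0083).

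Less secure were 3 of the named differences. LOC778362 was higher in IL-1_1 than in IL-1_4 by 4.48 ± 1.12 (limma adjusted p = 0.0165), but 0.0604 and 0.0728 without IL-1_4 replicates 2 and 3 and 0.112 with the axis covariate. LOC543597 was higher in IL-1_4 than in IL-2_3 by 2.77 ± 0.54 (0.0115), with 0.0869 and 0.062 without IL-1_4 replicates 1 and 2. RPB2 was higher in IL-1_4 than in IL-2_3 by 0.68 ± 0.14 (0.0142), with 0.101 and 0.0746 without IL-1_4 replicates 1 and 3, 0.0584 and 0.0542 without IL-2_3 replicates 1 and 3, and 0.0835 with only those 2 groups. Without the arrays with raised 3-prime to 5-prime control differences both LOC543597 (0.117) and RPB2 (0.125) were lost.

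In all, 1776 probe sets differed between IL-1_1 and IL-1_4, 492 between IL-1_1 and IL-2_3, and 156 between IL-1_4 and IL-2_3. The 1776 became 909 and 956 without IL-1_1 replicates 1 and 4, 736, 668 and 606 without IL-1_4 replicates 1, 2 and 3, 950 without the arrays with raised 3-prime to 5-prime control differences, and 730 with the axis covariate. The 492 became 787 without M82 replicate 1, 316 without IL-1_1 replicate 4, 310, 299 and 834 without IL-2_3 replicates 1, 2 and 4, 239 with only the 2 groups, and 873 without the 3 arrays lowest of their groups on the first component. The 156 became 239 with the axis covariate. Ethylene genes were higher in IL-1_1 than in IL-1_4 by the pattern list (median 0.24, camera adjusted p = 0.0141; adjusted p = 0.701 with an estimated correlation). They were higher than in IL-2_3 by both lists (0.26, adjusted p = 0.0141, and 0.23, adjusted p = 0.0371; adjusted p = 0.701 and 0.876 with an estimated correlation). Jasmonate and wound genes were lower in IL-1_4 than in IL-2_3 (median -0.28, camera adjusted p = 0.000919, and 0.876 with an estimated correlation). That list holds opr2 and was not tested without it.

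Few probe sets changed in the same way in more than 1 line. IL-1_1 and IL-1_4 shared 6, of which 2 were higher and 4 lower, and RAN2A was the only one with a symbol; 3 more were called in opposite ways. IL-1_1 and IL-2_3 shared 12, of which 6 were higher and 6 lower, and 1 went opposite ways; none carries a symbol. IL-1_4 and IL-2_3 shared 0 at the adjusted threshold of limma. In these lines 356 and 471 probe sets had an unadjusted limma p under 0.05. Both counts are below a share of 0.05 of the 10101 tested, which unchanged probe sets would give on average. They therefore do not by themselves point to weaker changes below the threshold. Simulated unchanged lines shared 0 in the median and at most 0. Lines without any change are expected to give few or no calls at this threshold, so little could be shared. That 0 therefore does not show how much overlap the shared M82 arrays would create between lists of the observed sizes. Independent lists of these sizes would share 0.831 higher and 3.02 lower for the first pair, 1.22 and 4.18 for the second, and 0.0245 and 0.371 for the third. With the M82 arrays divided between the lines the first pair shared a median of 0 (0 to 7), the second 2.5 (0 to 6) and the third 0 (0 to 1). The first pair shared 12 without M82 replicate 1 and 0 to 2 without M82 replicates 2, 3, 4 or 5, IL-1_1 replicates 1 or 4 or IL-1_4 replicates 2 or 3. The second shared 26 without M82 replicate 1 and 6 or 7 without M82 replicate 2, IL-1_1 replicate 4 or IL-2_3 replicates 1 or 3. The third shared 2 without IL-1_1 replicate 1 and 1 without IL-2_3 replicate 4. With only the compared groups fitted the first pair shared 3 and the second 1. Without the arrays with raised 3-prime to 5-prime control differences they shared 0 and 6. Without the 3 arrays lowest of their groups on the first component the 3 pairs shared 11, 23 and 5, and with the axis covariate 1, 19 and 3.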

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

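The tests of the 3 patterns weighed here and the limits set for the splits of the arrays were chosen after the results were seen, while the tests of line against line were set beforehand.

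The broad change of IL-1_1 was set against a technical cause and against a condition of the samples. The mean 3-prime minus 5-prime control difference gave no sign of RNA degradation in the IL-1_1 arrays. It was lower than that of M82 by -0.124, within the spread (exact two-sided permutation p = 0.248), and M82 replicate 5 alone reached 0.405. Single controls pointed different ways. The GlutTrans difference was lower in every IL-1_1 array than in any M82 array. The GAPDH difference was higher in IL-1_1 replicates 1 and 4 than in any M82 array but replicate 1. IL-1_1 replicates 2 and 3 lay within the M82 range. In each group the array with the highest GAPDH difference also had the highest axis score. M82 replicate 5 was high in GAPDH as well but scored low on the axis. RNA degradation is therefore not excluded. A condition axis that also varies among M82 and IL-2_3 arrays did not account for all calls as scored here. With the axis score as a covariate, 413 of 1233 calls stayed. The score is 1 linear measure that holds 51.6% of the variance within the M82, IL-1_4 and IL-2_3 groups. A condition that it measures only in part is therefore not excluded as the whole cause. The axis may be part of the cause: 87.5% of the calls have its direction and a median of 68% of the change was left. The higher IL-1_1 scores and the calls come from the same probe sets, so the shared direction is no separate evidence. The 820 calls that were lost went from a median absolute log2 change of 0.613 to 0.365 while their SE went from 0.166 to 0.137, so they ended because the change became smaller. Of 100 splits drawn from the 210 of the IL-1_1 and M82 arrays 4, the real one included, gave at least the real 1233, a share of the splits drawn that is under the 5% limit but too near it to exclude chance firmly, and the highest other gave 3807, which points to structure among the samples beyond the line.

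The falls of over 2-fold were set against a mismatch of probes to the introgressed allele, which would lower 1 probe set and spare others of the same transcript. Called falls of that size numbered 122 in IL-1_1, 38 in IL-1_4 and 45 in IL-2_3. Only falls with another probe set of the same transcript above the dimmest 25% in M82 could be assessed, with 1 fall taken per transcript. Other probe sets fell by under 50% as much in 46.7% of 15 falls in IL-1_1, 81.8% of 11 in IL-1_4 and 68.8% of 16 in IL-2_3, and with 95% intervals of 21.3 to 73.4, 48.2 to 97.7 and 41.3 to 89 a mismatch and a change of level cannot be told apart in any line. Among 35 rises of over 2-fold in IL-1_1 the share was 25.7%, and two-sided Fisher exact tests against it, added after those intervals left the question open, gave adjusted p of 0.191, 0.00441 and 0.00819. Which probe sets belong to the same transcript was inferred from probe set names and symbols by a rule set after a first listing was viewed, so paralogs, alternative forms and changes in part of a transcript stay open. For ARF3 in IL-2_3, 1 probe set fell by 5.01 and the other gave -0.07.

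The depth of the falls bears on whether the lines were hybrid or homozygous. Loss of signal from 1 of 2 equal alleles would lower the log2 value by at most 1, but 59 called falls in IL-1_1, 30 in IL-1_4 and 30 in IL-2_3 had a 95% interval below -1. At the inferred log base these falls are deeper than loss from 1 of 2 equal alleles would give. They were picked for their depth by unadjusted intervals, and none is known to lie in an introgressed segment. Hybrid and homozygous lines therefore cannot be told apart by them. Unequal alleles and effects of the segment on genes elsewhere were not tested. The rule for weighing these falls was changed after its first outcome, from a share of all calls to a share of the called falls below -1. By the first rule the 59 falls of IL-1_1 are set against all 1233 calls.

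Splits of the arrays into groups of the same sizes were run for the other comparisons as well. The share that reached the real count was under the 5% limit in each, and near it for IL-2_3 against M82. That limit was set after the results were seen, and the shares were not adjusted over the comparisons. Chance is therefore not firmly excluded for any of them. For IL-1_4 against M82, 1 of 84 splits reached the real count of 65, the real one itself, and the highest other gave 23. For IL-2_3 against M82, 4 of 100 drawn from 210 reached 91, the real one included, and the highest other gave 812, with M82 replicates 1, 3 and 6 set together with IL-2_3 replicate 4, which points to structure among the samples. For IL-1_1 against IL-1_4, IL-1_1 against IL-2_3 and IL-1_4 against IL-2_3, 1 of 35 splits, the real one, reached 1776, 492 and 156, and the highest others gave 762, 1 and 8. A share of 1 in 35 is the smallest that 35 splits allow.

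Values that stood apart from the rest of their group by Dixon's test numbered 4 of 102 tests on groups of 4 or 6 arrays, and chance sets about 1 in 20 groups apart. IL-2_3 replicate 4 had an axis score of 33.29, with -14.03 to -10.81 in the other IL-2_3 arrays. IL-2_3 replicate 2 had a median of 10.024, with 10.009 in the others, and a RAN2A level of 13.348, with 13.241 to 13.252 in the others. IL-2_3 replicate 1 had an ARF3 level of 5.841, with 4.99 to 5.1 in the others.

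Lines differed in their response, by limma tests of line against line, at 1776 probe sets for IL-1_1 and IL-1_4, 492 for IL-1_1 and IL-2_3 and 156 for IL-1_4 and IL-2_3. Of the 20 genes named by size for IL-1_1, 20 differed from IL-1_4 and 11 from IL-2_3, against 17.58% and 4.87% of all probe sets. These genes were chosen for extreme values in the same arrays, so a high share is no independent evidence. Of the 5 named for IL-1_4, 5 differed from IL-1_1 and 4 from IL-2_3, and of the 4 named for IL-2_3, 4 differed from IL-1_1 and 4 from IL-1_4. Ethylene genes differed by a median of 0.237 (pattern list) between IL-1_1 and IL-1_4, and by 0.263 (pattern list) and 0.225 (symbol list) between IL-1_1 and IL-2_3, at the preset correlation only (adjusted p = 0.701, 0.701 and 0.876 with an estimated correlation). Jasmonate and wound genes differed by -0.275 between IL-1_4 and IL-2_3, also at the preset correlation only (adjusted p = 0.876 with an estimated correlation).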

How the results depend on the processing

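No called named gene, and no list called in a line against M82, changed sign in any alternative that included it (0 reversals). The named calls tracked numbered 67. Sign changes of named genes that were called neither at first nor in the alternative were not counted. Lists between lines were run with the estimated correlation only. The balance of rises and falls did turn: IL-1_1 against M82 had 646 higher and 587 lower, but 638 and 726 with quantile normalization, 607 and 775 with median centring, 264 and 291 without the raised arrays described below and 252 and 285 with the axis covariate. With only the 2 groups fitted, IL-1_1 against IL-1_4 went from 849 higher and 927 lower to 977 and 847, and IL-1_4 against IL-2_3 from 83 and 73 to 84 and 91. Neither direction can be said to prevail in these comparisons. Quantile normalization, median centring and a variance trend moved no count of calls by more than 1.5 times. They kept 67, 65 and 67 of the named calls, and all 50 that remained were kept without the dimmest 25% of probe sets, where the pattern lists called in IL-2_3 went from 1 to 0 because the MADS-box list fell below the minimum of 5 probe sets and was not tested. With only the 2 groups compared in a fit, 377 probe sets were called in IL-1_1 against M82, 60 in IL-2_3 against M82 and 239 in IL-1_1 against IL-2_3. The probe sets shared with IL-1_4 and IL-2_3 by IL-1_1 then numbered 3 and 1, and 43 named calls stayed. Fewer arrays there leave fewer degrees of freedom. That alone does not account for every move, since both counts of IL-1_4 against IL-2_3 rose. A 2-group fit also takes its spread from those groups alone. The median SD of a probe set was 0.232 in M82, 0.221 in IL-1_1, 0.184 in IL-2_3 and 0.114 in IL-1_4. What each of these contributed was not tested. With a correlation estimated from the data, 0 pattern lists were called in IL-1_1 and 0 in IL-2_3, since camera then allows for the measured correlation within a list. Not run were the tests by chromosome and the counts without the introgressed chromosomes, for want of a table of positions.

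With the replicate number as a block, 815 probe sets were called in IL-1_1 against M82 (382 higher and 433 lower), IL-1_1 and IL-2_3 shared 7, 0 pattern lists were called in IL-2_3, and 53 named calls stayed. The block is not used elsewhere: 10 of 21 pairs of arrays with the same number in different groups had a correlation above 0.1, over a range of -0.705 to 0.605, and only 3 of 17 arrays were most like those of their own number. The block ended the calls of LOC778362 (adjusted p = 0.0691), yfe37 (0.0583), TDR4 (0.056), MAN2 (0.108), HSP21 (0.0545), CAT2 (0.0855), CIF1 (0.0509), COP1 (0.06), RAN2A (0.0825) and fsm1 (0.0548) in IL-1_1. It ended those of ribA (0.45) in IL-1_4, RPB2 (0.133) in IL-2_3, and LOC543597 (0.08) and RPB2 (0.0714) between IL-1_4 and IL-2_3. Also ended by the block were the calls of the jasmonate and wound list in IL-1_4 (median -0.10, adjusted p = 0.0775) and of the MADS-box pattern list in IL-2_3 (0.051). The cause was not tested.

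Chosen after seeing the data were 3 alternatives; what caused the moves was not tested for those that leave out arrays. Leaving out the 2 arrays with raised 3-prime to 5-prime control differences gave 555 calls in IL-1_1 against M82 and 950 against IL-1_4, with 0 and 6 shared with IL-1_4 and IL-2_3, and 43 named calls stayed. Leaving out 3 arrays, each the lowest of its group on the first component, gave 1916 in IL-1_1 against M82 and 873 against IL-2_3. The shared counts were then 11, 23 and 5 (the last for IL-1_4 and IL-2_3), and 1 pattern list was called in IL-1_4. With the axis of variation within groups as a covariate, 537 were called in IL-1_1 against M82, 104 in IL-1_4 against M82, 730 in IL-1_1 against IL-1_4 and 239 in IL-1_4 against IL-2_3. The shared counts were 1, 19 and 3, 0 pattern lists were called in IL-1_1 and 0 in IL-2_3, and 44 named calls stayed.

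Leaving out each array in turn kept 43 to 67 of the named calls. For IL-1_1 against M82 the count ran from 421 to 3079, for IL-1_4 against M82 from 48 to 70 and for IL-2_3 against M82 from 68 to 100. It ran from 606 to 2497 for IL-1_1 against IL-1_4, from 299 to 834 for IL-1_1 against IL-2_3 and from 111 to 182 for IL-1_4 against IL-2_3. Shared probe sets ran from 0 to 12 for IL-1_1 and IL-1_4, from 6 to 26 for IL-1_1 and IL-2_3 and from 0 to 2 for IL-1_4 and IL-2_3. Pattern lists called stayed at 1 in IL-1_1, and ran from 0 to 1 in IL-1_4 and from 0 to 2 in IL-2_3. The cause of these moves was not tested.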

Other observations

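Within M82 the arrays differed along an axis that held 51.6% of the variance within the M82, IL-1_4 and IL-2_3 groups, and the 10 genes of greatest weight on each side of it, among those with a symbol other than a LOC number, were picked after the values were seen and not tested as groups. On 1 side ACO6 ran from 4.843 to 10.867 among M82 arrays, the chitinase genes CHI3 from 5.624 to 10.497 and CHI17 from 8.127 to 11.137, PR-P2 from 5.241 to 8.559, ERF4 from 6.343 to 9.607, PTI4 from 7.697 to 10.892, TSW12 from 7.176 to 12.48, Eix1 from 5.143 to 9.829, twi1 from 5.748 to 10.08 and FESOD from 6.144 to 10.001. On the other the light-harvesting genes CAB5 ran from 5.248 to 9.376 and CAB4 from 10.167 to 13.559, the xyloglucan-modifying enzyme genes XTH1 from 11.277 to 13.82 and XTH6 from 4.966 to 7.365, and the expansin gene EXP2 from 8.152 to 10.341. The invertase gene LIN7 ran from 6.562 to 10.258, AGPL3 from 7.527 to 9.343, sph1 from 9.526 to 12.265, DDTFR18 from 8.458 to 10.945 and Xegip from 4.512 to 7.487. The 3 IL-1_4 arrays were close together, with ACO6 from 7.401 to 8.126 and CAB4 from 12.972 to 13.111. In IL-1_1 ACO6 ran from 10.423 to 12.016 and CAB4 from 10.271 to 13.124.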
